A study of Corynebacterium glutamicum R with 8 samples.

How the data were processed

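Total RNA from Corynebacterium glutamicum R, a soil bacterium used to make amino acids, was measured on 8 one-colour Agilent arrays. The cultures were the wild type and a mutant lacking pfkB1, grown with glucose or fructose and harvested at 4 h or 12 h, with 1 array per condition. Per the labels' protocols, cells grew at 33 degrees Celsius in 100 ml of medium with 4% sugar in a 500 ml flask, and 10 ug of RNA was turned into Cy3-labelled cDNA.

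Per the file headers, the deposited intensity values came from Agilent Feature Extraction, which subtracted the background and corrected spatial trends on each array. The headers give version 10.5.1.1 and the submitters' processing notes give 10.5.5.1. No between-array scaling is recorded in those intensities. The deposited value table of the authors holds log2 values. Set against the scanner files, each of its 40264 rows was the mean over spots of the log2 processed signal minus 1 constant per array, relative to the wild type on glucose at 4 h. The column medians were 0 for that array and -0.37, -0.59 and -0.07 for wild type fructose, mutant glucose and mutant fructose at 4 h. They were 0.39, 0.53, -0.17 and 0.29 for wild type glucose, wild type fructose, mutant glucose and mutant fructose at 12 h. Scale, centring and direction of that table are therefore known, and how its constants were chosen is not given in the sources used here.

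Each array had 45220 spots, of which 43803 were not controls. The 3278 probes with CGR numbers, each on 2 or 3 spots, stood for genes in all gene-level tests. A further 18462 forward and 18449 reverse tiles had 1 spot each, and their numbers followed an order: the correlation between neighbouring numbers of the 12 h minus 4 h change was 0.87 for forward and 0.86 for reverse tiles, against at most 0.02 in 100 shuffles of the numbers. The files do not pair probe IDs with gene names. None of the 40204 array IDs matched the reference gene table, which describes the strain ATCC 13032 (0 matches against 3079 genes). Probes are therefore given by ID, and the gene list tests planned before the data were examined were not run.

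The main values were the log2 processed signal minus each array's 75th percentile over non-control spots, without spots marked as outliers (10 to 42 per array), as the median over the spots of a probe. All 3278 CGR probes were well above background on all 8 arrays, so the filters on dim probes removed none. No spot was saturated. The 75th percentile of the signal ran from 1292 to 3535 and the negative control median from 3.95 to 7.33. The pooled SD between spots of a probe within an array was 0.097 to 0.172 on the log2 scale. The number of arrays limits the precision of every comparison.

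Gene-level tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with Benjamini-Hochberg adjustment at 0.05. Genotype, sugar and time entered an additive model of all 8 arrays, with 4 arrays on each side of a factor and 4 residual degrees of freedom. Its spread is array noise together with any interactions. Models with 1 interaction had 3 residual degrees of freedom and also gave the genotype effect within each sugar. Nothing in the labels says that arrays were repeated from separate cultures, so the p-values measure the spread between these arrays. Chance alone gives an unadjusted p under 0.05 for a share of about 0.05 of the 3278 probes. Array-wide differences shared by many probes can move such a count either way. Tests on tiles were run apart from the CGR probes and were chosen after the data were seen. Comparisons of single arrays give log2 differences and counts of probes at least 2-fold apart, with no test. All arrays at 4 h lay on slide 1 and scan 1 and all arrays at 12 h on slide 2 and scan 2, so no fit here separates time from slide.

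The fits were tested on simulated data with 200 of 3278 probes changed, in 10 simulated sets. For genotype, 20.8% of the probes changed by a log2 of 1 were recovered and 74.6% of those changed by 2. For the genotype effect on fructose the shares were 2.4% and 35.6%, and for the genotype by sugar interaction 0% and 1%. False calls made up 3.48% to 5.53% of the calls. The simulated noise was normal and independent between probes, with no array standing apart. The real arrays share differences across many probes, so these shares need not hold for them. The search for runs of at least 6 neighbouring tiles, each at least 2-fold above or below the median tile difference, recovered 40 of 40 planted runs. Each planted run was a constant value past the threshold, so this checks only that the search works as written. How many noisy runs it would miss was not tested.

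The probes named were those with the greatest rise and fall, past the threshold and with the same direction in all matched pairs, or by size where none passed. Because the IDs carry no gene names, at most 2 each way are printed per comparison. Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, other filters on dim probes, the mean over spots, the authors' value table, an intensity trend with robust variances, the matched conditions as a block, all 3 interactions together, and each array left out in turn. Normexp used the median spot and background signals, since no mean spot signal is among the columns used here. Subtraction of each array's floor (its 5th percentile of tile signals, with a floor of 0.02 after scaling), the 4 h arrays alone, median scaling of single-array comparisons, and all settings for tiles and for the signs and correlations of genotype differences were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.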

Results

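Transcript levels were compared between wild type Corynebacterium glutamicum R and a mutant lacking pfkB1, which encodes a phosphofructokinase of fructose breakdown. Both strains were grown with glucose or fructose and sampled at 4 h, in early log phase, and at 12 h. Per the series design text, the wild type was then in stationary phase and the mutant in late log or stationary phase. Each of the 8 conditions had 1 array and no replicate. The 75th percentile of the processed signal was 3535, 3318, 2309 and 1894 for wild type glucose, wild type fructose, mutant glucose and mutant fructose at 4 h. At 12 h, in the same order, it was 2926, 1962, 1292 and 2804. The ratio of the 75th to the 1st percentile of the signal differed between arrays, from 6.13 in wild type fructose at 12 h to 24.6 in mutant glucose at 4 h. Values below are log2 signals minus the array's 75th percentile, and gene names are not given because the files do not pair probe IDs with genes.

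A few neighbouring tiles were far lower in every mutant array than in every wild type array. Of 36911 tiles, 6 were at least 4-fold lower on average in the 4 mutant arrays than in the 4 wild type arrays, with no overlap, and 0 tiles were that much higher. Chance alone gives such an order, lower in every mutant array, for 1.43% of tiles. They were 4 neighbouring forward tiles and 2 neighbouring reverse tiles. Tile CGRfwd10944 averaged 0.95 ± 2.47 (SD, n = 4 arrays) in the wild type and was not well above background in any of the 4 mutant arrays (mean -8.39 ± 0.55), which is at least 174-fold lower in the mutant. Tile CGRrev07511 averaged -2.27 ± 0.18 in the wild type and was not well above background in the mutant (-8.97 ± 0.50), at least 18.7-fold lower. Of the 6 tiles, 2 remained well above background in all 4 mutant arrays. A fold limit of this kind sets the mean of the bright group against, per dim array, the higher of the probe's own signal and the dimmest signal well above background. In limma's genotype test on 36826 tiles, all 6 fell in the mutant (adjusted p 8.11e-19 for CGRfwd10944 and 1.09e-18 for CGRrev07511), and 4 tiles rose. No CGR probe met the same rule (0 of 3278). Which probes lie in pfkB1 is not recorded in the files, so these tiles were not placed in that gene.

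The 4 forward tiles lower in the mutant sat inside a run of 25 forward tiles, CGRfwd10937 to CGRfwd10961, whose other 21 tiles kept their signal in the mutant at 4 h. The run was chosen after its values were seen, on the difference between fructose and glucose in the wild type at 4 h. Over these 21 tiles the mean level at 4 h was 2.09 in the wild type on glucose, 3.77 in the wild type on fructose, 3.65 in the mutant on glucose and 4.72 in the mutant on fructose. The wild type was thus 3.19-fold higher on fructose than on glucose, with all 21 tiles higher. Each tile of the run had to lie at least 2-fold above the median tile difference of -0.44, so this direction was set by the choice. The mutant on glucose was 2.95-fold above the wild type, again in all 21 tiles. That comparison shares the wild type glucose array with the choice of the run. At 12 h the level was -0.99 in the wild type on glucose, -0.97 in the wild type on fructose and -1.32 in the mutant on glucose. The mutant on fructose stayed at 4.08, which is 33.3-fold above the wild type on fructose. That fold was 66.5 after quantile normalization, 67.4 with the array floor subtracted and 51.0 with normexp. The mutant was above the wild type on glucose at 4 h by 2.01-fold after quantile normalization and 4.54-fold with median scaling. The mutant fructose array at 12 h resembled the 4 h arrays over all CGR probes (r = 0.896 to 0.907). It was at least 4-fold apart from wild type fructose at 12 h for 296 CGR probes, so the difference at 12 h is not particular to this run. All values of the run describe single arrays and were not tested.

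**Figure D1:**
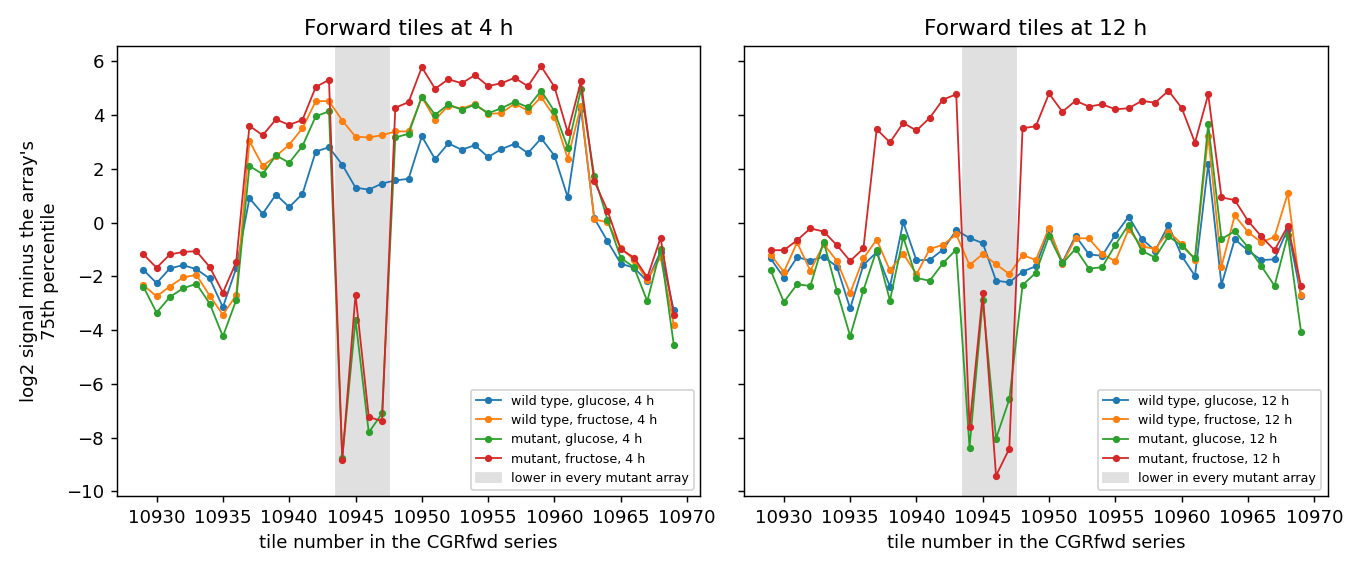
Log2 signal minus the array's 75th percentile for the forward tiles from 8 before CGRfwd10937 to 8 after CGRfwd10961, with the tile number on the x axis, at 4 h (left) and 12 h (right), where lines are single arrays and the grey band marks the 4 forward tiles that were lower in every mutant array. At 12 h only the mutant on fructose (mean 4.08) stands above the other cultures (-0.99, -0.97 and -1.32) on the tiles around the band. That array resembled the 4 h arrays over all CGR probes.

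A further run of 20 neighbouring reverse tiles, elsewhere in the numbering, was chosen after its values were seen, on the difference between mutant and wild type on glucose at 4 h. Its mean was 0.83 in the wild type on glucose, 2.26 in the wild type on fructose, 2.68 in the mutant on glucose and 3.09 in the mutant on fructose at 4 h. With median scaling the mutant was at 4.50 on glucose and 4.36 on fructose at 4 h, the reverse order. At 12 h, in the order of the 4 h values and with the 75th percentile, the values were -0.40, -0.37, -0.58 and 3.09. The last is again from the array that resembled the 4 h arrays over all CGR probes. The 4 tiles that rose in limma's genotype test all belonged to this run. That test includes the arrays on which the run was chosen, so the overlap is no separate support for it.

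For harvest time, all 4 cultures were compared between 12 h and 4 h. Between 4 h and 12 h, 1079 of 3278 CGR probes changed in limma, 569 rising and 510 falling, and 1021 of them by at least 2-fold. CGR0080 rose by 5.91 on the log2 scale (SE 1.16, adjusted p 0.00839) and CGR2996 by 5.48 (SE 1.03, adjusted p 0.00789), both higher at 12 h in 4 of 4 matched pairs. CGR1388 fell by 4.52 (SE 0.62, adjusted p 0.00512) and CGR1387 fell by 4.57 (SE 0.68, adjusted p 0.00513), both lower in 4 of 4 pairs. In the wild type on glucose, CGR0080 went from -2.56 at 4 h to 4.49 at 12 h, 132-fold, and in the mutant on glucose from -2.91 to 5.38. In the mutant on fructose it went only from -3.06 to -2.31. Of all CGR probes, 1924 (58.7%) moved the same way in all 4 matched pairs, against 12.5% for random signs. The median change was above 0 in every pair (0.28, 0.39, 0.41 and 0.18), and all pairs share the slides, so 12.5% is only a rough guide. The same share was 10.1% for genotype and 6.89% for sugar.

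The split into rising and falling probes depended on the scaling. The median time change of all CGR probes was 0.35 with the 75th percentile, 0.00 after quantile normalization and -0.17 with median scaling. The split of calls was 275 rising and 469 falling after quantile normalization, 50 and 654 with median scaling, and 246 and 405 with the array floor subtracted, so changes are best read relative to those medians. All arrays at 4 h shared a slide and scan, and so did all arrays at 12 h, so these fits cannot tell time from slide. The mutant fructose array at 12 h lay on the same slide as the other 12 h arrays, yet the change of that culture since 4 h had a slope of at most 0.221 on the changes of the other cultures. The count was 7 without the wild type fructose array at 4 h, 183 without wild type fructose at 12 h, 308 without mutant glucose at 4 h, 465 without wild type glucose at 12 h, 524 without mutant glucose at 12 h and 608 without wild type glucose at 4 h. It was 1555 without mutant fructose at 12 h. Without wild type fructose at 4 h none of the 4 named probes passed, with changes of 6.0 for CGR0080 (adjusted p 0.0657), 5.40 for CGR2996 (0.0645), -4.31 for CGR1388 (0.0538) and -4.42 for CGR1387 (0.0563). With the array floor subtracted CGR0080 also missed the threshold, with a change of 6.89 (adjusted p 0.0563). Over all alternatives the adjusted p ran from 4.73e-31 to 0.0657 for CGR0080, from 5.7e-27 to 0.0645 for CGR2996, from 2.38e-18 to 0.0538 for CGR1388 and from 1.06e-18 to 0.0563 for CGR1387.

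The mutant on fructose was the culture whose profile moved least between the times. At least 2-fold differences between 12 h and 4 h were found for 1132 probes in the wild type on glucose, 1888 in the wild type on fructose and 1579 in the mutant on glucose, but for 418 in the mutant on fructose. The SD of the log2 change was 1.39, 1.63 and 1.75 in the first 3 cultures and 0.725 in the mutant on fructose. Across CGR probes, which are not independent replicates, the changes of the first 3 cultures correlated at r = 0.85 to 0.95, and each correlated with that of the mutant on fructose at 0.35 to 0.42. The mutant fructose array at 12 h correlated at 0.896 to 0.907 with the 4 arrays at 4 h and at 0.620 to 0.668 with the other 12 h arrays. Those 3 other 12 h arrays correlated at 0.922 to 0.968 among themselves and at 0.502 to 0.637 with the 4 h arrays. In the mutant on fructose CGR1042 was 3.76 higher at 12 h and CGR1181 was -5.31 in log2 difference, 39.7-fold lower. Of the 418 probes, 180 were higher and 238 lower. With normexp the numbers were 941 and 213, and with median scaling 65 and 403.

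**Figure D2:**
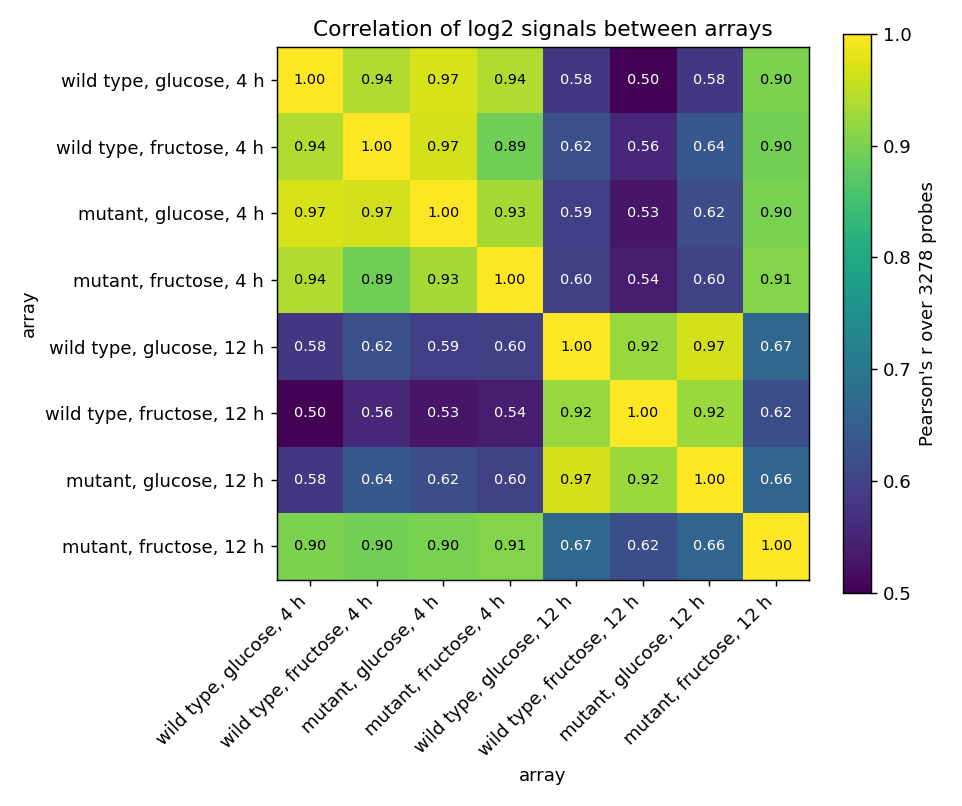
Pearson's r between the log2 signals of each pair of the 8 arrays over 3278 CGR probes, with the colour scale from 0.5 to 1. The mutant fructose array at 12 h lies at 0.896 to 0.907 with the 4 h arrays and at 0.620 to 0.668 with the other 12 h arrays.

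The other pairs of harvest times split as follows. In the wild type on glucose 569 probes were higher and 563 lower at 12 h, and 389 and 705 with median scaling. In the wild type on fructose 1167 were higher and 721 lower, 573 and 922 after quantile normalization and 339 and 1347 with median scaling. In the mutant on glucose 868 were higher and 711 lower, and 512 and 939 with median scaling.

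For genotype, the additive model of all 8 arrays gave 0 CGR probes past the threshold in limma, with 95 at an unadjusted p under 0.05. The greatest estimates were 2.36 for CGR2732 (SE 0.68, adjusted p 0.988, higher in 4 of 4 pairs) and 1.96 for CGR2546, and, on the low side, -1.56 for CGR0476 and -1.73 for CGR0080. None of these passed. With all 3 interactions fitted together, which leaves 1 residual degree of freedom, CGR2732 passed (2.36, adjusted p 0.00254). Without mutant fructose at 12 h the estimates were 1.53 for CGR2732, 0.47 for CGR2546, -0.23 for CGR0476 and 0.06 for CGR0080. CGR0476 was at -2.42 without wild type glucose at 4 h and -2.54 without mutant glucose at 12 h, and CGR0080 at -0.82 without wild type fructose at 12 h and -2.82 without mutant glucose at 12 h. CGR2732 stood at 0.00 in the wild type and 3.00 in the mutant on glucose at 4 h, and at 2.31 and 3.68 on fructose. At 12 h it was -1.40 and -1.38 on glucose, and -1.17 and 3.89 on fructose. The median genotype difference of all CGR probes was -0.05, and 0.15 with median scaling and 0.14 with normexp.

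On glucose the mutant and the wild type were at least 2-fold apart for 386 probes at 4 h and 382 at 12 h, and the differences at the times correlated at r = 0.59 across probes. Each of these differences also correlated with the mean signal level of the probes (r = 0.69 at 4 h and 0.68 at 12 h). After quantile normalization, with r of -0.06 and -0.03 with the level, the differences at the times correlated at 0.44. On fructose the numbers were 772 and 983, and the differences correlated at r = -0.03, and at 0.07 after quantile normalization. On glucose at 4 h, 84 probes were at least 2-fold higher in the mutant and 302 lower. CGR2732 was 7.97-fold and CGR0752 3.99-fold higher in the mutant, and CGR2376 (log2 difference -1.67) and CGR2040 (-1.55) were the lowest. The split was 37 higher and 7 lower after quantile normalization, 88 and 85 with normexp, 125 and 214 in the authors' value table, 926 and 1 with median scaling and 145 and 295 with the array floor subtracted. After quantile normalization the difference was -0.55 for CGR2376 and -0.47 for CGR2040. On fructose at 4 h, 406 probes were higher and 366 lower, 193 and 358 after quantile normalization and 121 and 748 with median scaling. There CGR0625 was 17.1-fold and CGR1441 15.7-fold higher in the mutant, while CGR2663 (-3.77) and CGR1042 (-3.24) were the lowest. At 4 h mutant glucose was at least 2-fold apart from wild type fructose for 191 probes, and mutant fructose from wild type glucose for 248.

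On glucose at 12 h, 269 probes were higher and 113 lower in the mutant, 93 and 9 after quantile normalization, 225 and 52 with normexp and 712 and 4 with median scaling. CGR1440 was 10.1-fold and CGR2123 7.95-fold higher, and CGR1141 (-1.64) and CGR2376 (-1.57) were the lowest. After quantile normalization the differences were 2.22 for CGR1440, 1.80 for CGR2123, -0.64 for CGR1141 and -0.67 for CGR2376. On fructose at 12 h, where the mutant array resembled the 4 h arrays, 523 probes were higher and 460 lower, 1120 and 336 with normexp and 665 and 321 with median scaling. CGR2546 was 73.5-fold and CGR1857 38.3-fold higher, and CGR0080 (-7.14) and CGR1440 (-6.13) were the lowest. Modelled over both times, limma's genotype effect had 0 probes past the threshold on fructose (315 at an unadjusted p under 0.05) and 0 on glucose (177). On fructose the count was 631 without mutant fructose at 4 h and 64 without mutant fructose at 12 h, and on glucose it was 5 with either of these arrays left out. With all 3 interactions fitted together and 1 residual degree of freedom the count on fructose was 33. With an array left out the mutant on fructose has 1 array, which limma assumes to vary like the other conditions.

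For sugar, limma gave 0 of 3278 CGR probes past the threshold, with 56 at an unadjusted p under 0.05. The greatest estimates were 2.60 for CGR1904 (SE 0.75, adjusted p 0.964) and 2.30 for CGR1905 (SE 0.73, adjusted p 0.964), higher on fructose in 4 of 4 pairs and not past the threshold. The lowest were -1.64 for CGR0477 and -1.92 for CGR0080. With all 3 interactions fitted together CGR1904, CGR1905, CGR0080 and CGR2732 passed, the last of which was chosen after its values were seen. Without mutant fructose at 12 h the estimates were 1.58 for CGR1904, 1.28 for CGR1905, -0.51 for CGR0477 and -0.13 for CGR0080. Without mutant glucose at 12 h they were -0.84 for CGR0477 and -0.82 for CGR0080. CGR1904 went from 1.16 on glucose to 3.60 on fructose in the wild type at 4 h, and from 2.95 to 4.07 in the mutant. At 4 h CGR0477 went from -1.41 to -1.35 in the wild type and from -1.765 to -2.06 in the mutant. CGR0080 then went from -2.56 to -2.73 in the wild type and from -2.91 to -3.06 in the mutant. The median sugar difference of all CGR probes was 0.00, and -0.14 with median scaling.

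Between the sugars within a strain and time, the wild type at 4 h had 139 probes at least 2-fold higher and 345 lower on fructose. CGR1003 was 5.86-fold and CGR1904 5.45-fold higher, and CGR1981 (-2.23) and CGR1441 (-2.19) were the lowest. After quantile normalization the difference of CGR1441 was -1.43. The split was 117 and 96 after quantile normalization and 623 and 66 with median scaling. In the wild type at 12 h 87 probes were higher and 126 lower, 130 and 389 after quantile normalization, 125 and 318 with normexp and 52 and 222 with median scaling. There CGR0599 was 8.03-fold and CGR1440 6.68-fold higher, and CGR0746 (-1.85) and CGR2544 (-1.84) were the lowest. In the mutant at 4 h 303 probes were higher and 334 lower, 107 and 212 after quantile normalization and 43 and 861 with median scaling. CGR1441 was 9.56-fold and CGR2252 5.62-fold higher, while CGR2663 (-3.48) and CGR1042 (-3.17) were the lowest. In the mutant at 12 h 643 probes were higher and 669 lower, 1155 and 554 with normexp and 370 and 896 with median scaling. CGR2546 was 72.9-fold and CGR1904 71.4-fold higher, and CGR0080 (-7.69) and CGR2997 (-7.02) were the lowest.

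**Figure D3:**
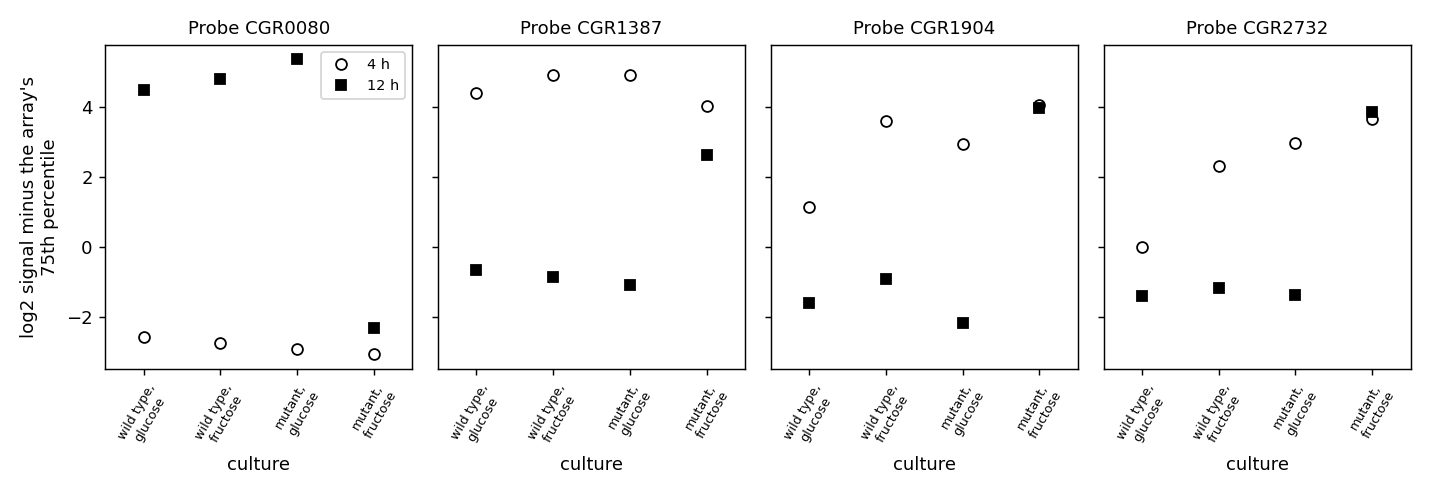
Log2 signal minus the array's 75th percentile (y axis) of 4 CGR probes in each culture, with open circles for 4 h and filled squares for 12 h, each a single array. CGR0080 stands at 4.49 to 5.38 at 12 h in every culture except the mutant on fructose (-2.31), and CGR2732 at 3.89 at 12 h in that culture against -1.40 to -1.17 in the others.

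The interactions asked whether an effect differed between levels of another factor. Genotype by sugar gave 0 CGR probes past the threshold in limma, with 395 at an unadjusted p under 0.05. The estimates were 3.61 for CGR2654 (SE 0.98) and 3.53 for CGR2653 (SE 0.68), each with an adjusted p of 0.404. On fructose at 4 h the mutant minus the wild type was 3.72 for CGR2654 and 3.61 for CGR2653, against -0.23 and -0.20 on glucose. After quantile normalization the differences on glucose were 0.19 and 0.07, and with median scaling 0.39 and 0.43. The lowest estimates were -4.62 for CGR1440, below 0 in 1 of 2 pairs, and -4.86 for CGR2123, below 0 in 2 of 2. They were -2.09 and -2.55 without mutant fructose at 12 h and -7.15 and -7.17 without mutant fructose at 4 h, and CGR1440 was at -2.85 without mutant glucose at 12 h. All 4 named probes passed with either mutant fructose array left out. With all 3 interactions fitted together 6 probes passed, CGR1440 and CGR2123 among them. Genotype by time gave 0 (9 at an unadjusted p under 0.05) and sugar by time gave 0 (106). The genotype by sugar count was 549 without mutant fructose at 4 h and 110 without mutant fructose at 12 h. Genotype by time gave 202 without mutant glucose at 12 h, and sugar by time gave 194 without wild type fructose at 12 h. Each of these fits leaves 1 combination of the factors tested with 1 array, which limma assumes to vary like the others.

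Against the wild type on glucose at 4 h, the reference the series design names, the number of probes at least 2-fold apart was 484 for wild type fructose, 386 for mutant glucose and 248 for mutant fructose at 4 h. At 12 h it was 1132 for wild type glucose, 1507 for wild type fructose, 1388 for mutant glucose and 415 for mutant fructose. CGR2997 was 176-fold higher in mutant glucose at 12 h, and CGR2123 107-fold higher in wild type fructose at 12 h. CGR2732 was 12.8-fold higher in mutant fructose at 4 h and 14.8-fold higher at 12 h. CGR0637 (-5.59) was the lowest in mutant glucose at 12 h, and CGR1181 (-4.43) the lowest in mutant fructose at 12 h. The wild type fructose array at 12 h had 842 higher and 665 lower, 693 and 897 after quantile normalization and 447 and 956 with median scaling. The mutant fructose array at 12 h had 200 higher and 215 lower, 972 and 179 with normexp and 86 and 383 with median scaling.

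**Figure D4:**
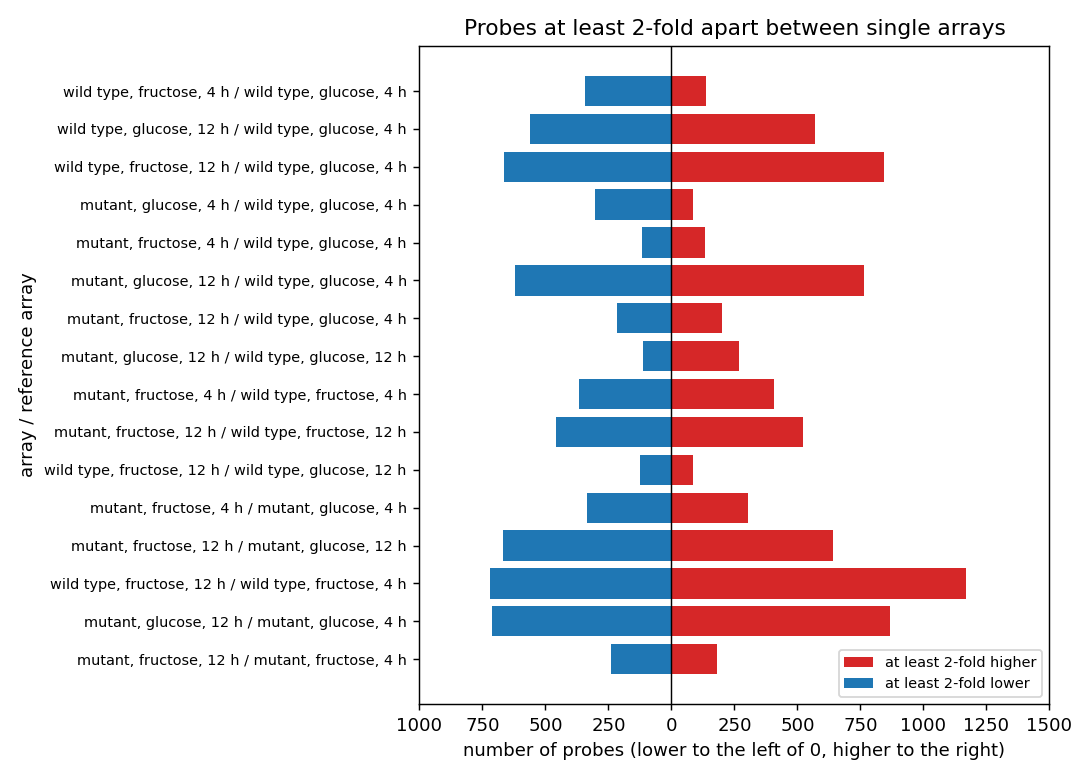
Number of CGR probes (x axis) at least 2-fold higher (red, right of 0) or lower (blue, left of 0) in each single-array comparison, labelled on the y axis as array over reference array. The greatest total is wild type fructose at 12 h over 4 h, with 1167 higher and 721 lower, and the 12 h over 4 h comparison of the mutant on fructose has 180 and 238.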

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

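The tests on tiles, the comparisons of arrays within a set, the tests of explanations and the counts over other splits were chosen after the results were seen, while the limma tests on CGR probes were planned. Arrays were compared within the 4 arrays of a genotype, sugar or time. In 48 such sets 6 had an array standing apart, where chance, at about 1 in 20, gives about 2.4. The sets hold the same arrays and related measures, so they are not independent and 2.4 is only a rough guide. Among the 12 h arrays, mutant fructose had a mean r of 0.650 with the 3 others. Among the mutant arrays the lowest mean r was 0.626 (mutant glucose at 12 h), and among the fructose arrays it was 0.572 (wild type fructose at 12 h). In each of these sets the other 12 h array was mutant fructose, which resembled the 4 h arrays. Mutant glucose at 12 h had a ratio of the 75th to the 1st percentile of 14.5, apart from the other 12 h arrays. Wild type fructose at 4 h had a negative control median of 7.33, apart from the other fructose arrays, and wild type fructose at 12 h had 10 outlier spots.

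With the 75th percentile, the mutant minus wild type difference of CGR2654 and CGR2653 was below 0 in both pairs on glucose and above 0 in both on fructose, with interaction estimates of 3.61 and 3.53. CGR2123 ran the other way, with -4.86. On glucose at 4 h CGR2654 and CGR2653 were above 0 after quantile normalization (0.19 and 0.07) and with median scaling (0.39 and 0.43), so their opposite signs depend on the scaling, while CGR2123 had opposite signs under all 5 scalings. None passed limma's interaction test (adjusted p 0.404 for each), though all 3 passed with either mutant fructose array left out, which leaves 1 array for that condition. Of 3278 probes, 717 (21.9%) had such opposite signs, against 16.0% if the signs on glucose were independent of those on fructose. After quantile normalization it was 759 (23.2% against 17.2%), of which 423 were among the 717. Tile CGRfwd10944 passed the genotype by time test (4.85, adjusted p 0.0025). It was not well above background in the mutant at either time. The estimate joins the fall of the wild type signal with a rise of those dim mutant values. They were -8.75 and -8.82 at 4 h, and -8.37 and -7.61 at 12 h. With 3 residual degrees of freedom limma gave this test 110500 in total, so the p-value rests on nearly 1 variance shared by all tiles.

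The mutant fructose array at 12 h resembled the 4 h arrays. A slide or scan effect as the whole change from 4 h to 12 h is argued against, because that array shares the slide of the other 12 h arrays and yet its change had a slope of at most 0.221 on theirs. After all arrays were given 1 distribution, 102 runs of at least 6 neighbouring tiles lay at least 2-fold apart between the mutant fructose arrays. Shuffles of the numbers gave at most 0 in 100. Neighbouring tiles lay about as far apart on the slide (median 158 spots) as shuffled ones (159). The arrays thus differed by more than independent noise of single spots. Shuffles break any likeness of neighbours, also one from processing, and no array pair is known to hold the same RNA. The runs therefore cannot decide whether both arrays held the same RNA, which stays open. A swap with a 4 h tube is argued against because no 4 h array had an r above 0.637 with the other 12 h arrays. Decay of 1 RNA between the slides, a wrong harvest time for this tube, and slower growth of the mutant on fructose, which the design text's growth phases allow, stay open and were not tested.

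At 4 h the mutant's changes on glucose and on fructose, which share no array, ran opposite ways (r = -0.41 across probes). The sugar changes of the strains, taken from the same 4 arrays, did too (r = -0.52). These are 2 views of 1 pattern and not separate observations. Giving the arrays 1 distribution moved r to -0.236 for genotype and -0.326 for sugar, so their signal range may account for part of the opposition, but not for all of it. A swap of the mutant tubes at 4 h cannot be told apart from an effect of the mutation, since the mutant fructose array at 12 h was nearer to the tube called fructose by an r of only 0.00858. Mutant fructose was at least 2-fold apart from wild type glucose for 248 probes and from wild type fructose for 772, while mutant glucose was nearer to wild type fructose (191) than to wild type glucose (386), though not after quantile normalization (92 and 44) or with normexp (219 and 173), nor by r (0.967 and 0.969). A genotype effect that depends on the sugar stays open, and limma's interaction test had 0 probes past the threshold and 395 at an unadjusted p under 0.05. By chance a share of about 0.05 of the 3278 probes lies there. The probes share array-wide differences, so the 395 is no measure of such an effect.

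The stretch around the tiles lower in the mutant, chosen on a change that shares the wild type glucose array, was higher in the mutant on glucose at 4 h by 1.56 on the log2 scale. Signal range as the whole cause is argued against, since the difference was 1.01 ± 0.20 (SD over 21 tiles) after all arrays were given 1 distribution. Read-through from those tiles in every condition is argued against by a difference of -0.33 ± 0.35 on glucose at 12 h (0.11 ± 0.46 after quantile normalization). A swap of the mutant tubes at 4 h, which stays open, would exchange the levels 3.65 and 4.72. The mutant would then be further above the wild type on glucose (2.09), and no higher than the wild type on fructose (3.77). Such a swap would thus widen the difference on glucose and not account for it. Read-through that needs an active promoter and an effect of the mutation stay open and were not tested.

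The 8 arrays were also split in other ways. For time, 1 of 33 splits, the real one, gave 1079 probes, and the highest other split gave 331. This argues against chance but cannot exclude it, since the real split alone is already 1 of 33. A slide effect that makes up part of the change cannot be excluded either. For genotype and for sugar the real split gave 0 probes, which all 33 of 33 splits reach by construction, so the count of splits tests nothing there. The highest other split gave 222 in the genotype set and 41 in the sugar set. In the genotype set it was the sugar split with mutant glucose and mutant fructose at 12 h exchanged. In the sugar set it was the time split with mutant fructose at 4 h and at 12 h exchanged. Both exchanges involve mutant fructose at 12 h, the array that resembled the 4 h arrays. These splits were picked as the highest, and the cause of their counts was not tested.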

How the results depend on the processing

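Floor subtraction, median scaling of single-array comparisons and the 4 h arrays alone were chosen after the data were seen. Arrays without replicates, unequal signal floors and the sharing of slides by time limit all results, and the cause of the differences below was not tested. The gene list alternatives were not run, for want of a table pairing probes with genes. The filters on dim probes removed 0 probes and so say nothing about stability. Of the model counts under alternatives, 129 stayed within 1.5 times and on the same side, 8 moved and 12 went from 0 to calls. Of the 129, 118 were 0 under both settings and say nothing about stability, and the other 11 were time counts. Of the named probes in the models, 418 values kept direction and side of the threshold. Only the 4 time probes had a call in the main fit, so the other probes had no call to keep. A further 28 values gained a call. The sign changed for 1 with neither value past the threshold: genotype of CGR0080, from -2.82 to 0.0596 over the arrays left out, the latter without mutant fructose at 12 h. The call was lost for 5: the 4 time probes without wild type fructose at 4 h, and CGR0080 with the floor subtracted (adjusted p 0.0563). The time changes of these probes were 6.0, 5.40, -4.31 and -4.42 for CGR0080, CGR2996, CGR1388 and CGR1387 without that array, and 6.89 for CGR0080 with the floor subtracted. Of the single-array counts 100 stayed within 1.5 times and 44 moved. Most of the 44 came from the 1.5-fold and 4-fold cut-offs, which change a count by definition and not through processing. Among the 100 are the counts with the filter on dim probes, which could not move. Of the named single-array differences 166 kept within 1 SD, 218 moved and 0 changed sign.

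With all 3 interactions fitted together, which leaves 1 residual degree of freedom, limma called 1 probe for genotype (CGR2732), 4 for sugar (CGR1904, CGR1905, CGR2732 and CGR0080), 6 for genotype by sugar and 33 for genotype on fructose averaged over both times, against 0 for each. The time count of 1079 was 704 with median scaling and 651 with the floor subtracted. Leaving out 1 array at a time gave 7 to 1555 for time, 0 to 0 for genotype and for sugar, 0 to 549 for genotype by sugar, 0 to 202 for genotype by time, 0 to 194 for sugar by time, 0 to 631 for genotype on fructose and 0 to 5 for genotype on glucose. Where this leaves a condition or a combination of factors with 1 array, that array is assumed to vary like the others.

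The number of probes apart between single arrays moved as follows. After quantile normalization it was 213 for fructose against glucose in the wild type at 4 h, 519 at 12 h and 319 in the mutant at 4 h, and for mutant against wild type on glucose it was 44 at 4 h and 102 at 12 h. With normexp, mutant against wild type on glucose at 4 h gave 173, fructose against glucose in the wild type at 12 h gave 443, and mutant fructose at 12 h gave 1151 against wild type glucose at 4 h and 1154 against mutant fructose at 4 h. With median scaling, mutant against wild type on glucose gave 927 at 4 h and 716 at 12 h. With the floor subtracted, mutant fructose at 4 h gave 498 against wild type glucose at 4 h. Mutant fructose at 12 h then gave 838 against wild type glucose at 4 h, 1635 against wild type fructose at 12 h and 729 against mutant fructose at 4 h, and fructose against glucose in the wild type at 12 h gave 759.

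At 1.5-fold and at 4-fold in place of 2-fold, the counts against wild type glucose at 4 h were 1332 and 11 for wild type fructose, 1347 and 1 for mutant glucose and 820 and 19 for mutant fructose at 4 h, and 1889 and 421 for wild type glucose and 1274 and 34 for mutant fructose at 12 h. Mutant against wild type gave 1430 and 13 on glucose at 12 h, 1720 and 75 on fructose at 4 h and 1723 and 296 on fructose at 12 h. Fructose against glucose gave 928 and 5 in the wild type at 12 h, 1622 and 29 in the mutant at 4 h and 2047 and 426 in the mutant at 12 h. The mutant on fructose at 12 h against 4 h gave 1218 and 52. At 4-fold alone the count moved to 482 for wild type fructose and 644 for mutant glucose at 12 h against wild type glucose at 4 h. For 12 h against 4 h it moved to 619 in the wild type on fructose and 685 in the mutant on glucose.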

Other observations

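All tests reported in this part were chosen after the data were seen. Neighbouring CGR numbers moved together between 4 h and 12 h, with a correlation of 0.44 between next numbers, against at most 0.04 in 100 shuffles. For the mean level the correlation was 0.32, and shuffles gave at most 0.05. The numbers thus carry an order in which probes near each other have like signals. On the tiles, the time test of limma called 14105 of 36826, 10600 rising and 3505 falling. The median time change of all tiles was 0.68, so this split depends on the scaling, and no other scaling was run for it. Relative to the median tile difference, runs of neighbouring tiles were more often lower at 12 h. There were 84 higher and 269 lower in the wild type on glucose, and 90 and 518 on fructose. In the mutant there were 146 and 375 on glucose, and 11 and 129 on fructose.

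Of the 21 tiles that passed the genotype test on fructose in limma, 16 were higher in the mutant, and 15 of these lay neither in the forward run CGRfwd10937 to CGRfwd10961 nor in the run of 20 reverse tiles.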
